A study of Homo sapiens with 10 samples.

How the data were processed

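Poly(A) RNA was extracted from SNU-387 cells and made into stranded libraries, and per the submitters' processing notes the reads were handled with CASAVA 1.8.2, Trimmomatic 0.35 and STAR 2.5.1b on the build GRCh38. The annotation release used for counting was not given in the sources used here. Each deposited table holds read counts per gene for a single library, as whole numbers without normalization, counted without regard to strand, on the strand of the read and on the opposite strand. The opposite-strand counts were used, because 92.2% to 94.5% of the reads assigned to genes by strand fell there in every library. Reads that align to several places are not among the gene counts, so genes with near-identical copies are measured by their distinct parts and their values are less certain.

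Gene identifiers were matched to GENCODE release 29 without their version numbers: 57836 of 58174 matched, and 0.0165% of gene counts lay on the others. The tables list 58219 identifiers, and 45 copies in the pseudoautosomal part of chromosome Y, which held 5 counts in all, were left out. The lines for unmapped, multimapping, unassigned and ambiguous reads name no gene and stayed out of library sizes and tests. They held 20.7% to 30.0% of the 13334692 to 21348889 reads of a library, and the counts in genes came to 10168307 to 16939029 per library. Depth of this order limits genes below about 1 CPM more than abundant ones.

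The groups were taken from the labels: 5 libraries with wild-type YES and 5 with YES T348I, all from cells treated with 100 nM dasatinib. The sample titles come in 2 styles, 3 and 2 per genotype, which were treated as possible batches. Before the data were examined, the design, the gene lists, the rule for naming genes and the alternatives were fixed, except where a choice is stated to have come later. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total count 15), scaled by TMM, and tested with the quasi-likelihood F test in a model of title set and genotype. Adjusted p-values are Benjamini-Hochberg values over the 13743 genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were calculated back from the test, as the absolute log2 fold change over the square root of its F statistic. The biological coefficient of variation was 0.130. CPM values are gene counts scaled to a common library size after TMM normalization, given as mean ± SD over 5 libraries per genotype. The genotype by title set interaction was tested in the same way, and each set was also fitted alone. The replicate numbers in the titles were not taken to pair the libraries and entered no main result.

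The 30 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, for the 27 lists with at least 5 tested members. An estimated correlation and fry were the alternatives. Members are counted as higher or lower at an adjusted p under 0.05 over all genes tested, and again with the adjustment over the list alone. Several lists overlap, such as ERK output and immediate-early genes in EGR1, and SNU-387 cells express matrix and fibroblast markers of their own.

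Genes were named by a rule. It takes YES1, all members of the YAP list, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean log2 CPM of at least 1 and the same sign in both title sets, and from each list up to 4 called members with the lowest p in its main direction and up to 2 in the other. The rule gave 148 genes, some of which are not reported here. Levels of some genes are also given per library where a library stood apart.

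The tests were checked on simulated counts drawn from the means, dispersions and library sizes of the real data. In the genotype test, over 13743 genes, 8% of 50 genes changed 1.25-fold were recovered, 64% of those changed 1.5-fold, 78% of those changed 2-fold and 98% of those changed 4-fold, and 6.77% of calls were false. In the interaction test over the same genes the recovery was 0%, 4%, 26% and 74%, so a small difference between title sets would be missed. Of the calls in that test 10.3% were false. In the list test, 9 of 9 lists shifted 1.3-fold and 1 of 18 unshifted lists were called, with the preset and with the estimated correlation. Real genes of a list vary together, which the simulated ones did not. The simulated libraries were also drawn independently, with the same dispersion of a gene in every library. The real T348I long-title libraries differ far less from each other than the wild-type ones, so the shares of false calls do not cover that feature.

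The alternatives were RLE size factors, library sizes alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter at 1 CPM in 5 libraries, no title set term, each title set alone, the replicate number as a block, and leaving out each library. After the data were examined, unstranded counts, leaving out both wild-type libraries that stand apart, a correction for GC content and exon length, and the sum of the T348I long-title libraries as 1 library were added, and the list interaction was run again without wild-type long-title library 1. Every per-library count column of the tables was mapped to its library, and the same-strand column served only to check strandedness.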

Results

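The series addresses signalling by the tyrosine kinase YES in liver cancer. RNA was sequenced from SNU-387 cells, an established line derived from a pleomorphic hepatocellular carcinoma, which stably expressed either wild-type YES or YES with the gatekeeper substitution T348I. YES, encoded by YES1, is a kinase of the SRC family, and dasatinib is a drug that inhibits SRC-family and ABL kinases. A gatekeeper residue lines the pocket in which such drugs bind, and its substitution is known to lower their binding to related kinases. All 10 libraries, 5 per genotype, came from cells treated with 100 nM dasatinib. The comparison therefore asks which transcripts differ when cells under the drug carry the mutant rather than the wild-type kinase. No untreated library was analysed here, so the values do not show how either genotype responded to the drug. The sample titles follow 2 styles, called long-title (3 libraries per genotype) and short-title (2 per genotype) here, and this title set entered the model as a batch term.

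The wild-type long-title libraries 1, 2 and 3 held 13849091, 10168307 and 11241103 reads in genes, and the wild-type short-title libraries 1 and 2 held 11705037 and 15135952. The T348I libraries held 15079250, 14836132 and 10420099 in the long-title set and 13354607 and 16939029 in the short-title set. Title sets separated along component 1 of log2 CPM, the read counts scaled by library size, with 50.5% of the variance, and genotypes along component 2, with 22.4%. Among the wild-type libraries, long-title library 1 stood apart from the other long-title libraries, with 492 genes at least 2-fold above their mean and 330 at least 2-fold below it. Wild-type long-title libraries 2 and 3 lay at least 2-fold apart in 394 genes. Library 2 also stood apart, with 8.64% of its reads unmapped. The 3 T348I long-title libraries differed from each other by little more than counting noise, with a chi-square per degree of freedom of 1.62 to 2.15 over genes. The same measure was 8.14 between the T348I short-title libraries, 29.3 between the wild-type short-title libraries and 14.1 to 54.2 between the wild-type long-title libraries. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

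**Figure D1:**
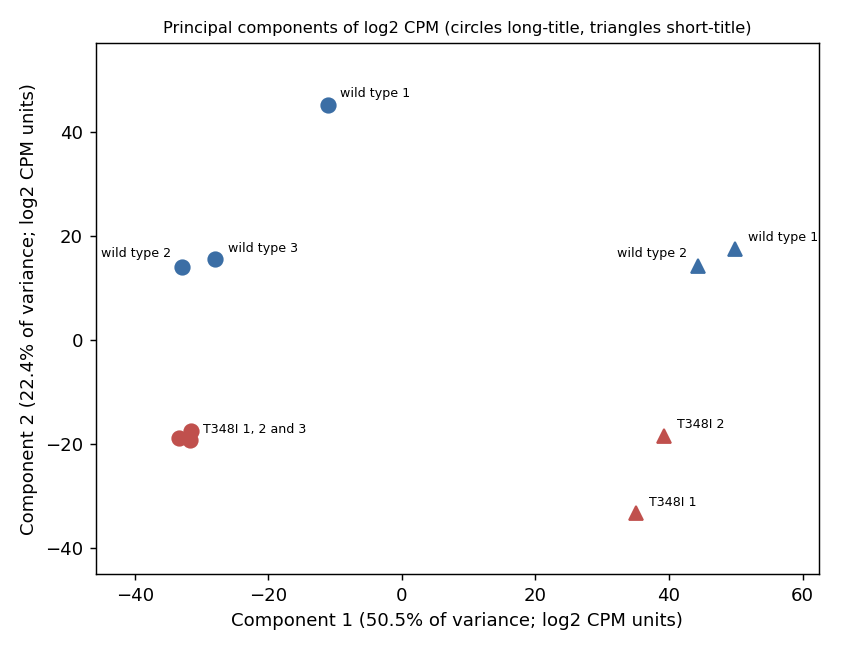
Each point is a library placed by components 1 and 2 of log2 CPM, in log2 CPM units, with wild type in blue, T348I in red, circles for long-title and triangles for short-title libraries. Title sets part along component 1, genotypes along component 2, and wild-type long-title library 1 lies highest on component 2, at 45.3 against 14.2 and 15.6 for the other long-title wild-type libraries.

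YES1 transcripts were counted in every library, at 303 ± 102 CPM (mean ± SD, n = 5) in wild-type and 453 ± 86.4 CPM in T348I libraries. The log2 fold change was 0.59 ± 0.19 (SE; edgeR adjusted p = 0.0326). The gene, ENSG00000176105.13, lies on chromosome 18 from 721588 to 812546 on the minus strand of GRCh38. Its counts combine the endogenous gene with the construct and do not show the substitution, so they check expression of YES1 and not the genotype. Wild-type libraries ranged from 208 to 454 CPM and T348I libraries from 313 to 547 CPM, so the groups overlapped. The log2 fold change was 0.45 in the long-title libraries alone (adjusted p = 0.257) and 0.82 in the short-title libraries alone (adjusted p = 0.0290). The difference between the sets did not pass its test (adjusted p = 0.997). The call ended without the title set term (adjusted p = 0.126) and with the T348I long-title libraries summed into 1 library (adjusted p = 0.109). It also ended without wild-type short-title library 1 (adjusted p = 0.0783) or 2 (0.0819), T348I long-title library 1 (0.0522), 2 (0.0546) or 3 (0.0637), or T348I short-title library 1 (0.112).

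Cells with YES T348I held more transcript of the collagenase gene MMP1 and of SEMA7A, a membrane ligand of the semaphorin family, than cells with wild-type YES. MMP1 rose from 1.53 ± 1.24 to 7.35 ± 2.62 CPM, a log2 fold change of 2.42 ± 0.28 (edgeR adjusted p = 9.84e-05). SEMA7A rose from 3.81 ± 0.878 to 15.7 ± 4.59 CPM (2.02 ± 0.19, adjusted p = 4.77e-05). Among the 10 largest rises were also the E3 ubiquitin ligase gene MARCH4 (2.32 ± 0.20, adjusted p = 4.72e-05), the hedgehog-binding HHIP (2.06 ± 0.21, adjusted p = 5.66e-05) and the LIM domain gene ZNF185 (1.92 ± 0.22, adjusted p = 7.88e-05). Transcripts of PDK4, a kinase that inhibits pyruvate dehydrogenase, fell from 8.08 ± 4.93 to 1.82 ± 1.247 CPM (-2.19 ± 0.32, adjusted p = 0.000354). The collagenase gene MMP13 (-2.16 ± 0.40, adjusted p = 0.00163) was also among the 10 largest falls. The fatty acid transporter gene CD36 (-1.99) and the aldehyde dehydrogenase gene ALDH3A1 (-1.93) fell as well. Without the title set term their adjusted p was 0.0504 and 0.167.

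Of 13743 genes tested, 1884 were higher and 1825 lower in T348I libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 26.99% of those tested. In 352 genes the difference was at least 2-fold, 109 upward and 243 downward. The median absolute log2 fold change of the called genes was 0.49. With the T348I long-title libraries summed into 1 library, a setting added after the data were seen, 899 genes were higher and 563 lower. Of those 1462, 1444 were also called in the same direction over all 10 libraries. Without the title set term 818 genes were higher and 497 lower. Leaving out T348I short-title library 1 gave 1108 lower genes, and leaving out T348I long-title library 1 gave 1204. Of the 138 called genes that the naming rule selects besides YES1, 58 lost their call with the libraries summed. Called genes given with a genotype fold change and its SE, but without such a statement, kept their call with the libraries summed, without the title set term and without each library in turn.

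**Figure D2:**
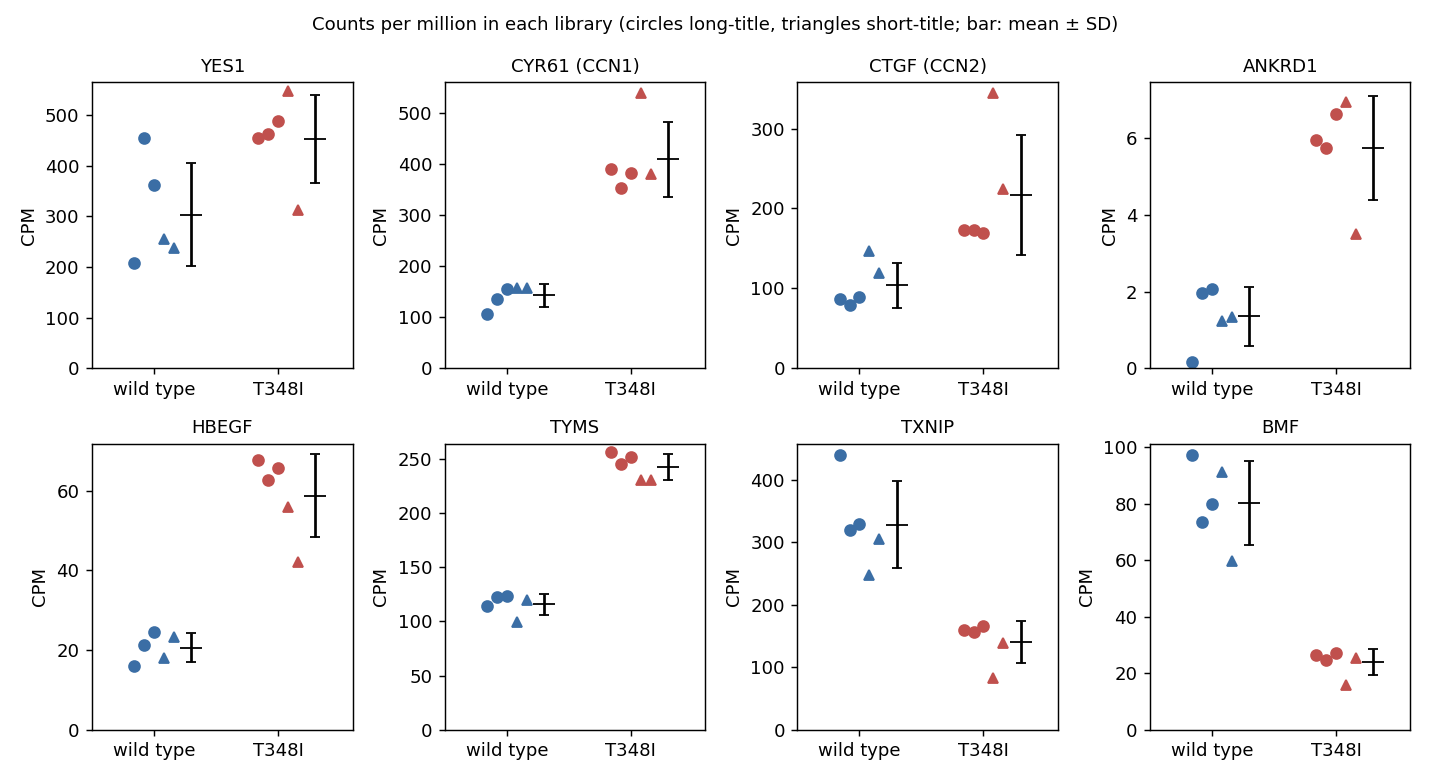
Each panel shows the CPM of a gene in each library of the wild-type (blue) and T348I (red) cells, with circles for long-title and triangles for short-title libraries, and a bar for the mean ± SD (n = 5). The panels for CYR61, CTGF, ANKRD1, HBEGF and TYMS show higher values in T348I libraries and those for TXNIP and BMF lower values, while the YES1 values of the groups overlap.

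YES is known to act on the transcriptional coactivator YAP, and targets of YAP, its paralogue TAZ and their TEAD partners were the main list. The matricellular gene CYR61 (CCN1) rose from 143 ± 22.3 to 409 ± 73.8 CPM (1.52 ± 0.11, adjusted p = 2.25e-05, edgeR). CTGF (CCN2), of the same family, rose from 104 ± 28.2 to 217 ± 74.9 CPM (1.05 ± 0.11, adjusted p = 5.45e-05). ANKRD1, a gene widely used as a readout of YAP, rose from 1.35 ± 0.760 to 5.75 ± 1.36 CPM (2.10 ± 0.36, adjusted p = 0.00118). AMOTL2, a negative regulator of YAP (1.09 ± 0.16, adjusted p = 0.000346), FJX1 (1.07 ± 0.14, adjusted p = 0.000205) and the ectonucleotidase gene NT5E (0.84 ± 0.10, adjusted p = 0.000125) also rose. Smaller rises were seen in F3, the gene of tissue factor (0.67 ± 0.15, adjusted p = 0.00561), and GADD45A (0.45 ± 0.08, adjusted p = 0.00188). In the list 12 of the 21 tested members rose and 0 fell, or 13 and 1 adjusted over the list alone. The median log2 fold change was 0.34 and the camera adjusted p was 3.31e-06, or adjusted p = 0.145 with an estimated correlation. The remaining called members were AXL (0.70), CRIM1 (0.39), DOCK5 (0.34) and the YAP-inhibiting kinase gene LATS2 (0.34). Without the title set term their adjusted p was 0.143, 0.172, 0.219 and 0.0746, and with the T348I long-title libraries summed DOCK5 and LATS2 reached 0.0786 and 0.0719. The call of LATS2 also ended without wild-type short-title library 1 (adjusted p = 0.0682) or 2 (0.0702), T348I long-title library 1 (0.0629) or 3 (0.0533), or T348I short-title library 1 (0.0826). Members with values on the other side included ARHGEF17 (-0.40 ± 0.16, adjusted p = 0.0749), RBMS3 (-0.14) and IGFBP3 (-0.080), none of which passed the test over all genes. ARHGEF17 passed without wild-type long-title library 2 (-0.53, adjusted p = 0.00390), without the low-count filter (adjusted p = 0.00121), without both wild-type libraries that stand apart (0.00546) and after the GC content and length correction (0.0400). It was -0.25 without wild-type long-title library 1 (adjusted p = 0.149). Uncalled members passed upward in edgeR without that library: MYOF (0.39, adjusted p = 0.00447), NUAK2 (0.57, 0.0197), ASAP1 (0.29, 0.0126), CCDC80 (0.26, 0.0159) and TGFB2. MYOF also passed in other settings, among them DESeq2, limma-voom and library sizes alone. IGFBP3 had values of 0.047, 0.018 and 0.038 without wild-type long-title library 1, wild-type short-title library 2 and T348I short-title library 1, and RBMS3 0.021 without the first of these.

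Most tested transcripts of the list that ERK, the last kinase of the RAS pathway, is known to induce rose in T348I cells. FOSL1, a subunit of the AP-1 factor, rose from 65.9 ± 12.4 to 171 ± 37.6 CPM (1.36 ± 0.14, adjusted p = 4.99e-05, edgeR). The ephrin receptor gene EPHA2 rose from 99.8 ± 28.8 to 182 ± 20.5 CPM (0.90 ± 0.12, adjusted p = 0.000218). EGR1 (0.92 ± 0.12, adjusted p = 0.000234) and the pathway's feedback inhibitor SPRY4 (0.70 ± 0.10, adjusted p = 0.000333) rose too. In this list 10 of the 16 tested members rose and 0 fell, or 11 and 0 adjusted over the list alone. The median was 0.56 and the camera adjusted p 3.03e-05, or adjusted p = 0.199 with an estimated correlation. Compared with the other long-title wild-type libraries, wild-type long-title library 1 lay lower in these genes, by a median of -0.35 on the log2 scale. Of the immediate-early genes, which share EGR1 with that list, 5 of the 17 tested members rose and 1 fell, or 5 and 1 adjusted over the list alone. The immediate-early list did not pass camera (median 0.30, adjusted p = 0.0943; 0.315 with an estimated correlation), and its median was 0.15 without wild-type long-title library 2 and 0.18 without T348I long-title library 3.

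Several ligands of growth factor receptors rose. HBEGF, a ligand of the EGF receptor, rose from 20.6 ± 3.56 to 58.8 ± 10.4 CPM (1.496 ± 0.13, adjusted p = 4.72e-05, edgeR). The neuregulin gene NRG1 rose from 20.7 ± 6.27 to 38.9 ± 12.4 CPM (0.89 ± 0.18, adjusted p = 0.00339) and FGF2 from 33.5 ± 6.04 to 58.1 ± 13.3 CPM (0.79 ± 0.15, adjusted p = 0.00238). In the list of receptors and growth factors 7 of the 15 tested members rose and 0 fell, or 7 and 1 adjusted over the list alone. Its median was 0.20 and its camera adjusted p 0.009998, or adjusted p = 0.145 with an estimated correlation. The median was 0.37 without wild-type long-title library 1, 0.32 without its library 3 and 0.32 without wild-type short-title library 1. All 7 called members encode ligands. EREG, another EGF receptor ligand, was called over all libraries (0.46 ± 0.11, adjusted p = 0.00639). It was not called with the T348I long-title libraries summed (adjusted p = 0.0696) or without the title set term (0.316).

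Part of the targets of SRF and its actin-regulated MRTF partners rose as well. The cytoplasmic actin gene ACTB went from 4881 ± 896 to 7172 ± 895 CPM (0.56 ± 0.10, adjusted p = 0.00142, edgeR) and ACTG1 from 2212 ± 331 to 3264 ± 311 CPM (0.56 ± 0.09, adjusted p = 0.000866). FHL2 (1.04 ± 0.24, adjusted p = 0.00757) and the tropomyosin gene TPM4 (0.32 ± 0.08, adjusted p = 0.0101) were higher over all libraries. With the T348I long-title libraries summed their adjusted p was 0.0600 and 0.0785. In this list 9 of the 18 tested members rose and 1 fell, or 11 and 1 adjusted over the list alone. The median was 0.33 and the camera adjusted p 0.000748, or adjusted p = 0.248 with an estimated correlation. Focal adhesion components went both ways, since 3 of the 21 tested members rose and 2 fell, or 3 and 3 adjusted over the list alone. Their median was -0.018, their mean 0.0086 and the camera direction upward, which did not pass (adjusted p = 0.836; 0.916 with an estimated correlation). The median was -0.061 without wild-type long-title library 2, 0.0098 without library 1 and 0.011 without T348I long-title library 1. Caveolin-1 (CAV1) was higher (0.46 ± 0.08, adjusted p = 0.000863) and the integrin gene ITGAV lower (-0.38 ± 0.09, adjusted p = 0.00752). Neither was called without the title set term (adjusted p = 0.331 and 0.303), nor was ITGAV with the libraries summed (0.118).

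Genes of DNA replication rose together. Thymidylate synthase (TYMS) rose from 116 ± 9.67 to 243 ± 12.03 CPM (1.07 ± 0.07, adjusted p = 1.16e-05, edgeR). The ribonucleotide reductase subunit RRM2 rose from 184 ± 33.9 to 402 ± 38.6 CPM (1.13 ± 0.11, adjusted p = 4.77e-05). The helicase factor CDC45 (1.09 ± 0.11, adjusted p = 4.99e-05) and UHRF1, which maintains DNA methylation (1.06 ± 0.10, adjusted p = 4.77e-05), rose by similar factors. All 26 tested members of the G1/S list rose, also adjusted over the list alone, with a median of 0.85 and a camera adjusted p of 3.36e-20. Of the 26 mitotic genes 24 rose and 0 fell, or 26 and 0 adjusted over the list alone, with a median of 0.57 and a camera adjusted p of 3.11e-17. Each list had an adjusted p = 0.145 with an estimated correlation. The mitotic kinase gene AURKB (0.85 ± 0.08, adjusted p = 4.81e-05), the transcription factor gene FOXM1 (0.80 ± 0.09, adjusted p = 7.65e-05) and BIRC5, the gene of survivin (0.75 ± 0.07, adjusted p = 4.77e-05), were among the mitotic genes that rose. In wild-type long-title library 1 these lists lay below the other long-title wild-type libraries, by a median of -0.45 for G1/S and -0.24 for mitotic genes, and both lists kept their calls without it.

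Most ribosome biogenesis factors rose, by smaller steps. BOP1, which processes the large-subunit ribosomal RNA, went from 25.3 ± 3.89 to 42.5 ± 5.06 CPM (0.75 ± 0.12, adjusted p = 0.000563, edgeR). RRS1 (0.74 ± 0.11, adjusted p = 0.000482), RRP9 (0.64 ± 0.11, adjusted p = 0.00104) and dyskerin, DKC1 (0.59 ± 0.10, adjusted p = 0.000973), rose too. In the list 17 of the 22 tested members rose and 0 fell, or 21 and 0 adjusted over the list alone. The median was 0.39 and the camera adjusted p 8.11e-09, or adjusted p = 0.248 with an estimated correlation. Library 1 of the wild-type long-title set lay lower in these genes, by a median of -0.31. MYC, a regulator of such genes and a member of the list of STAT3 targets, rose from 26.0 ± 3.47 to 50.2 ± 6.82 CPM (0.95 ± 0.11, adjusted p = 0.000111). Among the STAT3 targets 3 of the 11 tested members rose and 1 fell, or 3 and 1 adjusted over the list alone. That list did not pass camera (median 0.030, adjusted p = 0.491; 0.652 with an estimated correlation), and its median ranged from -0.012 without wild-type short-title library 1 to 0.052 without T348I long-title library 1.

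Enzymes of serine and asparagine synthesis were among the rising genes activated by ATF4, the factor of the amino acid response. PSAT1 rose from 112 ± 38.6 to 246 ± 67.8 CPM (1.15 ± 0.12, adjusted p = 5.45e-05, edgeR). Asparagine synthetase (ASNS) rose from 40.3 ± 11.4 to 78.5 ± 13.5 CPM (0.98 ± 0.13, adjusted p = 0.000216). PHGDH, the entry enzyme of serine synthesis, rose from 153 ± 30.0 to 254 ± 51.2 CPM (0.73 ± 0.08, adjusted p = 7.65e-05). In the list 9 of the 17 tested members rose and 0 fell, or 10 and 1 adjusted over the list alone. The median was 0.47 and the camera adjusted p 0.000766, or adjusted p = 0.326 with an estimated correlation. Here too wild-type long-title library 1 lay lower, by a median of -0.40. Without that library the list's median was 0.29. Other stress and metabolic lists did not pass camera over all libraries. Among the ER chaperones 3 of the 16 tested members rose and 1 fell, or 4 and 1 adjusted over the list alone (median 0.047, camera adjusted p = 0.576; median 0.0020 without wild-type long-title library 3). Among the cholesterol genes 0 of the 22 tested members rose and 3 fell, or 0 and 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.368). Without wild-type long-title library 1 the cholesterol list passed camera downward (median -0.17, adjusted p = 0.0182), and without library 2 the median was -0.030 (adjusted p = 0.488). Among the hypoxia and glycolysis genes 1 of the 18 tested members rose and 2 fell, or 1 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.562; median -0.079 without wild-type long-title library 1). With an estimated correlation each of these 3 lists had an adjusted p of 0.879. The glucose transporter gene SLC2A1 was the member that rose in the last list (0.47 ± 0.08, adjusted p = 0.00141; 0.138 without the title set term).

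**Figure D3:**
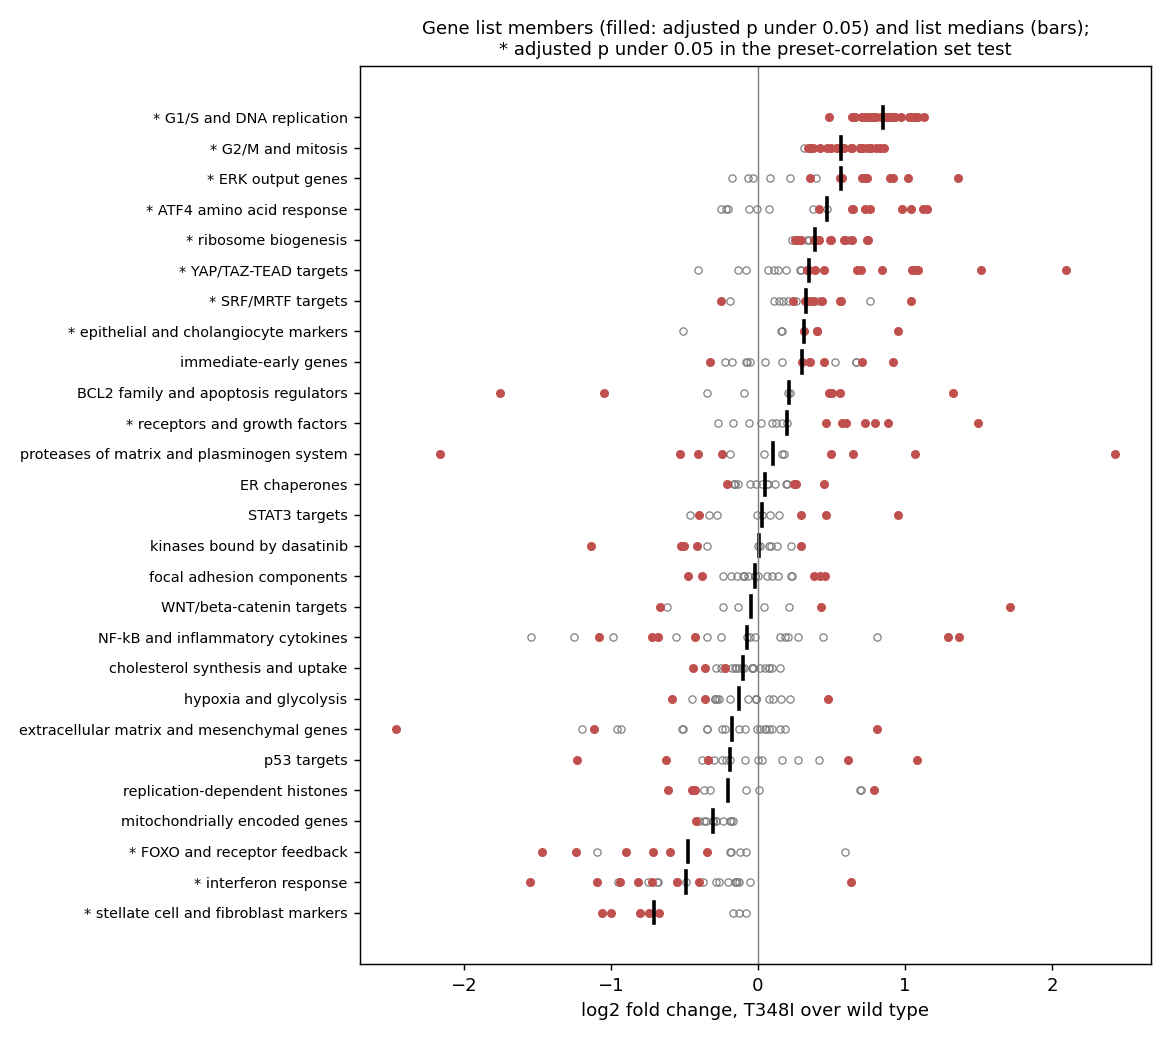
Each point is a tested member of a gene list at its log2 fold change, T348I over wild type, filled red where its adjusted p was under 0.05, and each bar is the list's median; an asterisk marks lists called by camera with the preset correlation. All members of the G1/S list lie to the right of 0, and the medians of the FOXO, interferon and stellate cell lists lie at -0.47, -0.49 and -0.71.

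Part of the genes activated by FOXO factors, which growth factor signalling through AKT holds in check, fell. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell from 329 ± 69.9 to 141 ± 34.2 CPM (-1.24 ± 0.14, adjusted p = 7.65e-05, edgeR). PIK3IP1, an inhibitor of PI3 kinase, fell from 16.9 ± 4.41 to 6.02 ± 1.64 CPM (-1.47 ± 0.14, adjusted p = 4.88e-05) and the cyclin gene CCNG2 from 44.4 ± 9.93 to 27.01 ± 5.10 CPM (-0.71 ± 0.13, adjusted p = 0.00182). In the list 0 of the 12 tested members rose and 6 fell, or 1 and 7 adjusted over the list alone. The median was -0.47 and the camera adjusted p 0.00105, or adjusted p = 0.145 with an estimated correlation.

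Regulators of apoptosis in the BCL2 family changed in both directions. Of the death-promoting members, BMF fell from 80.2 ± 14.8 to 23.8 ± 4.66 CPM (-1.76 ± 0.14, adjusted p = 4.24e-05, edgeR) and BCL2L11 (BIM) from 64.6 ± 15.99 to 31.3 ± 5.63 CPM (-1.04 ± 0.16, adjusted p = 0.000580). The survival genes BCL2L1 (0.56 ± 0.08, adjusted p = 0.000400) and BCL2 (1.33 ± 0.27, adjusted p = 0.00335) rose, the latter from a low level of 0.790 ± 0.168 CPM. MCL1, another survival gene (0.48 ± 0.08, adjusted p = 0.00103), and the death-promoting PMAIP1 (0.50 ± 0.08, adjusted p = 0.000862) were higher over all libraries. Without the title set term their adjusted p was 0.178 and 0.109. In the list 4 of the 10 tested members rose and 2 fell, or 4 and 2 adjusted over the list alone. The list did not pass camera (median 0.21, mean 0.0061, adjusted p = 0.368; 0.521 with an estimated correlation). Among p53 targets 2 of the 17 tested members rose and 3 fell, or 2 and 3 adjusted over the list alone. AEN, an apoptosis-enhancing nuclease, rose (1.08 ± 0.11, adjusted p = 4.99e-05) and the p53-induced TP53INP1 fell (-1.23 ± 0.15, adjusted p = 0.000154). The median of p53 targets was -0.19, with a camera adjusted p of 0.701 (0.879 with an estimated correlation). It lay nearest 0 without wild-type long-title library 1, at -0.084.

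Part of the interferon response genes fell. STAT2, a subunit of the interferon-activated factor ISGF3, went from 155 ± 23.5 to 93.9 ± 7.54 CPM (-0.72 ± 0.10, adjusted p = 0.000320, edgeR). Its partner gene IRF9 went from 2.53 ± 0.479 to 1.17 ± 0.498 CPM (-1.10 ± 0.26, adjusted p = 0.00835; 0.0543 with the T348I long-title libraries summed). OAS3, an antiviral oligoadenylate synthase, rose from 58.2 ± 11.8 to 90.7 ± 4.12 CPM (0.64 ± 0.12, adjusted p = 0.00163). In the list 1 of the 23 tested members rose and 7 fell, or 1 and 10 adjusted over the list alone. The median was -0.49 and the camera adjusted p 0.00625, or adjusted p = 0.674 with an estimated correlation. In wild-type long-title library 1 these genes lay above the other long-title wild-type libraries, by a median of 0.79, with 9 of 23 members at least 2-fold higher. Without that library the list's median was -0.13 and its adjusted p 0.0868. The list passed camera in the long-title libraries alone (median -0.67, adjusted p = 0.000617) but not in the short-title libraries alone (-0.24, 0.0897).

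Of the NF-kB and cytokine genes 2 of the 21 tested members rose and 4 fell, or 2 and 7 adjusted over the list alone. The cytokine gene IL11 rose from 9.61 ± 6.35 to 25.0 ± 5.09 CPM (1.37 ± 0.33, adjusted p = 0.00832, edgeR). LIF, of the same family, rose by 1.29 ± 0.13 (adjusted p = 4.99e-05; 0.224 without the title set term). The list did not pass camera, with a median of -0.076 and a downward direction (adjusted p = 0.838; 0.936 with an estimated correlation). The median ranged from -0.15 without wild-type long-title library 2 to -0.021 without library 1. Fry gave the list an upward direction (adjusted p = 0.942). The NF-kB list lay higher in wild-type long-title library 1 than in its fellow libraries, by a median of 0.93.

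Matrix genes moved with wild-type long-title library 1. Fibronectin (FN1) fell from 12667 ± 7600.0 to 5668 ± 518 CPM (-1.12 ± 0.25, adjusted p = 0.00556, edgeR). Its value was 26236 CPM in that library against a mean of 9638 CPM in the other long-title wild-type libraries, and it kept its call without that library. The collagen gene COL3A1 was lower in T348I libraries (-2.46 ± 0.76, adjusted p = 0.0292), with 883 CPM in library 1 against 52.3 CPM in the same libraries. Without library 1 its log2 fold change was -0.90 (adjusted p = 0.000236) and that of FN1 -0.73. In the matrix list 1 of the 22 tested members rose and 2 fell, or 1 and 2 adjusted over the list alone. The list did not pass camera (median -0.18, adjusted p = 0.701; 0.916 with an estimated correlation). In library 1 it lay above its fellow libraries by a median of 1.27, with 15 of 22 members at least 2-fold higher. The list's median turned to 0.073 without that library and was -0.29 without library 2. The call of COL3A1 ended without T348I long-title library 1 (adjusted p = 0.0865), 2 (0.0844) or 3 (0.0837) and without T348I short-title library 1 (0.0626). It ended without the title set term (0.229), with limma-voom (0.0607) and with the T348I long-title libraries summed (0.248), which also ended that of FN1 (0.0804).

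Among matrix proteases and their regulators 4 of the 12 tested members rose and 4 fell, or 4 and 4 adjusted over the list alone. MMP1 rose and MMP13 fell, as above. The gelatinase gene MMP2 went from 1384 ± 406 to 949 ± 161 CPM (-0.53 ± 0.11, adjusted p = 0.00388, edgeR), with an adjusted p of 0.0652 with the libraries summed and 0.104 without the title set term. The list did not pass camera (median 0.11, adjusted p = 0.701; 0.916 with an estimated correlation). Its median ranged from 0.027 without wild-type short-title library 1 to 0.20 without wild-type long-title library 1. In wild-type long-title library 1 it lay higher than in its fellow libraries, by a median of 0.39.

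Part of the markers of stellate cells and fibroblasts fell in T348I cells. Lumican (LUM) fell from 121 ± 48.7 to 55.7 ± 9.26 CPM (-1.06 ± 0.17, adjusted p = 0.000746, edgeR). Decorin (DCN) fell from 29.4 ± 21.2 to 13.8 ± 9.003 CPM (-0.999 ± 0.18, adjusted p = 0.00156; 0.349 without the title set term). In the list 0 of the 8 tested members rose and 5 fell, or 0 and 5 adjusted over the list alone. The median was -0.71 and the camera adjusted p 0.00789, or adjusted p = 0.210 with an estimated correlation. The list lay higher in wild-type long-title library 1, by a median of 0.44, and kept its call without that library. It passed camera in the long-title libraries alone (median -0.85, adjusted p = 0.00106) but not in the short-title libraries alone (-0.43, 0.137).

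Epithelial and bile duct markers rose in part. Keratin 7 (KRT7) went from 30.2 ± 4.68 to 58.5 ± 5.64 CPM (0.95 ± 0.11, adjusted p = 7.65e-05, edgeR). In the list 4 of the 7 tested members rose and 0 fell, or 4 and 0 adjusted over the list alone. The median was 0.31 and the camera adjusted p 0.0385, or adjusted p = 0.315 with an estimated correlation. The call ended without wild-type long-title library 1 (adjusted p = 0.149) or 2 (0.107), wild-type short-title library 1 (0.0928), or T348I long-title library 2 (0.0575) or 3 (0.0565). This list passed camera in the long-title libraries alone (median 0.26, adjusted p = 0.00776) but not in the short-title libraries alone (0.26, 0.125). Few markers of other cell types were counted highly enough to test. Of the hepatocyte markers 4 were tested and 1 fell, AMBP (-0.99 ± 0.26, adjusted p = 0.0139). Of the endothelial markers 2 were tested and 1 fell, PECAM1 (-1.15 ± 0.28, adjusted p = 0.00985). Of the leukocyte markers 2 were tested and 1 fell, CD14 (-1.58 ± 0.48, adjusted p = 0.0279). The counts were the same adjusted over each list alone, and no set test was run on these lists over all libraries. In the short-title libraries alone the hepatocyte list did not pass camera (median -0.55, adjusted p = 0.255). With the T348I long-title libraries summed the adjusted p of these genes was 0.0878, 0.0927 and 0.224, and without the title set term that of AMBP and CD14 was 0.156 and 0.103. The log2 fold change of CD14 was -0.68 without wild-type long-title library 1 (adjusted p = 0.00474). Its call also ended without T348I long-title library 1 (0.0876), 2 (0.0785) or 3 (0.0740) or T348I short-title library 1 (0.0505).

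Kinases that dasatinib is known to bind showed no joint change that passed the test. The receptor gene PDGFRB fell from 6.93 ± 3.38 to 3.18 ± 0.726 CPM (-1.13 ± 0.29, adjusted p = 0.0114, edgeR; 0.0790 with the T348I long-title libraries summed). In the list 1 of the 12 tested members rose and 4 fell, or 1 and 4 adjusted over the list alone. Its median was 0.0079, its mean -0.17 and its camera direction downward (adjusted p = 0.701; 0.916 with an estimated correlation). In wild-type long-title library 1 this list lay higher by a median of 0.51, and without that library PDGFRB had a value of -0.74. The list's median was 0.11 without wild-type long-title library 1, -0.084 without wild-type long-title library 2 and -0.037 without wild-type short-title library 1. Among the WNT targets 2 of the 8 tested members rose and 1 fell, or 2 and 3 adjusted over the list alone. The WNT inhibitor gene DKK1 rose (1.71 ± 0.18, adjusted p = 5.61e-05; 0.0680 without the title set term) and TBX3 fell (-0.66 ± 0.13, adjusted p = 0.00220). The WNT list had a median of -0.047, a mean of 0.092 and an upward camera direction (adjusted p = 0.838; 0.916 with an estimated correlation), and a median from -0.18 without T348I long-title library 3 to 0.00036 without T348I short-title library 2. Of the mitochondrially encoded genes 0 of the 13 tested members rose and 1 fell, or 0 and 0 adjusted over the list alone (median -0.30, camera adjusted p = 0.0682; 0.866 with an estimated correlation). The mitochondrial list passed camera downward without wild-type short-title library 2 (median -0.39, adjusted p = 0.00360) or T348I long-title library 1 (-0.35, 0.0306), and its median was -0.075 without wild-type short-title library 1 (adjusted p = 0.445). It also passed without the title set term (adjusted p = 0.0415), with the replicate block (0.0149) and with the T348I long-title libraries summed (0.0353). Of the replication-dependent histone genes, which poly(A) selection samples poorly, 1 of the 10 tested members rose and 3 fell, or 1 and 3 adjusted over the list alone. Their median was -0.20 and the camera adjusted p 0.368 (0.866 with an estimated correlation), and the median was -0.096 without T348I short-title library 1.

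Across the 27 lists with at least 5 tested members, camera with its preset correlation called 12, of which 9 rose and 3 fell. With an estimated correlation it called 0, with a smallest adjusted p of 0.145 and 6 lists at an unadjusted p under 0.05. Fry, which tests each list by itself and not against other genes, called 14, of which 11 were among those 12. The interferon list did not pass fry (adjusted p = 0.154). The immediate-early (fry adjusted p = 0.00900), BCL2 family (0.00191) and STAT3 (0.0431) lists passed it upward, though not camera.

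The long-title and short-title sets share no library, so they give separate values of the genotype difference. HBEGF rose by 1.66 in the former and 1.26 in the latter, TYMS by 1.06 and 1.08, and CYR61 by 1.49 and 1.55. BMF had values of -1.68 and -1.85. The long-title libraries alone gave 698 higher and 499 lower genes (3 against 3) and the short-title libraries alone 935 and 599 (2 against 2), all by edgeR at an adjusted p under 0.05. Of the genes tested in both, 500 were called higher and 200 lower in both sets, against 48.6 and 21.4 for independent lists of these sizes. Across 13192 genes, which are not independent replicates, the log2 fold changes of the sets correlated at Pearson r = 0.681 and Spearman rho = 0.693. Of the 3637 genes called over all libraries and fitted in both sets, 3635 had the same sign in each. This count is not independent of the calls, which use the same libraries. The edgeR test of the difference between the sets called 0 genes, with 459 at an unadjusted p under 0.05 and a smallest adjusted p of 0.509. DESeq2 called 1, the growth factor gene TGFA, named here after its value was seen (adjusted p = 0.000558). Its edgeR log2 fold change was 1.003 in the long-title and -0.058 in the short-title libraries.

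**Figure D4:**
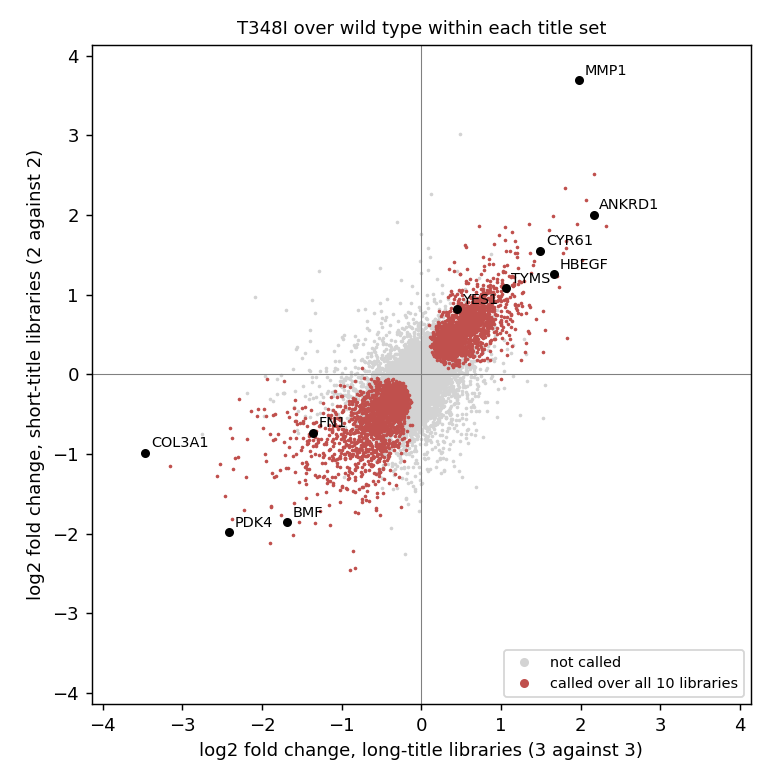
Each point is a gene at its log2 fold change (T348I over wild type) in the long-title libraries, 3 against 3, on the horizontal axis and in the short-title libraries, 2 against 2, on the vertical axis, red where called over all 10 libraries. CYR61, HBEGF and TYMS lie in the upper right and BMF, PDK4 and COL3A1 in the lower left, with COL3A1 at -3.47 and -0.98.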

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

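The tests of a swap with a T348I library, of other splits with the T348I long-title libraries summed or within title sets, of the YES1 ratio over all long-title libraries, of the T348I short-title pair and of the list interaction without wild-type long-title library 1 were chosen only after the results were seen, and the condition on the spread of the YES1 ratio was added after its value was seen.

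Other splits of the 10 libraries into 5 and 5 called far fewer genes than the genotypes did. Of 100 splits drawn, the real split included, 1 called as many genes: the real split called 3709 and the highest other 1043. For genes changed at least 2-fold the count was 2 of 100, with 352 for the real split and 401 for the highest other. That other split set wild-type long-title library 1 with all 4 short-title libraries, so with the title set term it compared this library with the rest of its set; within the sets the real genotypes gave 237 and 327 such genes. Of all 60 splits that keep 3 long-title and 2 short-title libraries in each group, 1 gave as many as the real split in either count, with 2 genes called and 0 changed at least 2-fold as the highest others. Chance is argued against for both counts if the 10 libraries are separate samples. A share of 1 in 60 is the smallest that these splits can give. Most of the 60 part the T348I long-title libraries, so they cannot exclude chance if those are not separate samples.

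The 3 T348I long-title libraries differed little from each other, so splits that part them call few genes. With these summed into 1 library, 1 of all 56 splits into 5 and 3, and 1 of the 24 among them that keep 1 long-title and 2 short-title libraries in the smaller group, called as many genes as the real split. The real split called 1462 and the highest other 1307. Over all 56 splits the real one called the most genes. A share of 1 in 24 is the smallest that the splits within title sets can give, so chance is not excluded there. For genes changed at least 2-fold, 2 of 56 splits and 2 of those 24 gave as many, with 247 for the real split and 288 for the highest other. Chance is not excluded within title sets for this count either. That highest other split in both counts set wild-type long-title library 1 and both wild-type short-title libraries apart, which kept the genotypes of the short-title set separate. Chance differences between cultures are not covered, as the labels do not say which libraries share one. For the number of lists over all 10 libraries chance is not excluded, since 17 of 100 splits, and 14 of the 60 within title sets, called as many as the 12 of the real split, and the highest other called 15.

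A candidate explanation for the genes called between genotypes is the higher YES1 level of the T348I libraries, in place of the substitution. Wild-type long-title library 1 had the lowest YES1. Without it, YES1 differed among the long-title libraries by 0.250 ± 0.137 (SE) times as much as among the short-title libraries. The genes called in the latter kept a slope of 0.644, more than a response in proportion to YES1 transcript would give. With library 1 included the ratio was 0.554 ± 0.322 and the slope 0.744, a difference within the error. With a further library left out besides library 1, the ratio ranged from 0.0595 to 0.462 and the slope from 0.636 to 0.653. The highest ratio, 0.462 with a slope of 0.649, came without wild-type library 2, which left a single wild-type long-title library. The lowest ratio came with wild-type library 2 alone. Its YES1 level of 454 CPM lay close to the 454 to 488 CPM of the T348I long-title libraries. The gap between slope and ratio thus rests on leaving library 1 out and keeping library 2. The test therefore does not decide on a response in proportion to YES1. GC content and exon length are argued against, since 95.66% of called genes kept their call and direction after both trends were removed. A response to the YES1 level, in proportion or not, differences between the stably expressing cell populations and the substitution itself stay open. Only a single wild-type library was matched for YES1 level, and no untreated cells were analysed here.

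Wild-type long-title library 1 differed from its fellow libraries in matrix, cytokine and interferon genes. A swap with a T348I library is argued against, because every T348I library correlated better with another T348I library of its set than with any wild-type library, by at least 0.004724. Cells of a stellate or fibroblast type stay open: lumican rose by 8.718% of the rise of COL3A1 in that library while decorin, another abundant transcript of such cells, was lower (35.7 against 48.6 CPM), which lies between the bounds set for and against them. Lower output of what separates the genotypes stays open as well. The library's deviation correlated across genes with the short-title fold changes at -0.237 (Spearman -0.286), against 0.0527 for wild-type long-title library 2 minus 3. ERK, G1/S, mitotic, ribosome biogenesis and ATF4 genes lay lower in it. YAP targets lay higher, by a median of 0.15, SRF targets lay at 0.0002 and FOXO genes at -0.11, none of which goes with lower output. Without it the long-title median of the YAP list went from 0.26 to 0.56. The YES1 level of wild-type long-title library 1, 208 CPM, was the lowest of the 10 libraries.

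The T348I short-title libraries stood apart from each other along part of the genotype difference. Across 13305 genes the difference, 1 minus 2, correlated with the long-title fold changes at r = 0.3746 (Spearman 0.400), against 0.0103 for the wild-type short-title pair. GC content and exon length are argued against, as 100.1% of r remained after their trends were removed. The median difference, 1 minus 2, was 0.24 for YAP targets, 0.25 for ERK output genes, 0.50 for ATF4 genes and -0.35 for interferon genes. It was only 0.086 for G1/S genes. Mitotic genes, at -0.087, and mitochondrially encoded genes, at 0.31, went against their genotype difference. Library 1 held 547 and library 2 held 313 CPM of YES1, so more output of the construct in library 1 may account for part of the pattern. It rests on a single pair, chosen for this pattern, and unequal exposure to the drug was not tested.

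In 27 of 292 combinations of gene and genotype a library lay far from the other 4. There the gap to its nearest neighbour, over the range of all 5, was above 0.71. For 5 libraries drawn from a single population chance would give about 1 in 20, or 14.6 here. The libraries of a genotype fall into 2 title sets that were not adjusted for, so 27 cannot be weighed against that number. Among the wild-type libraries, long-title library 1 was the lowest for MARCH4 (0.771), ANKRD1 (0.767), TP53INP1 (0.798) and NRG1 (0.760) and the highest for MMP13 (0.889), TGFB2 (0.761) and FN1 (0.875). Among the T348I libraries, short-title library 1 was the highest for MARCH4 (0.735), SEMA7A (0.923), CYR61 (0.761), FOSL1 (0.713), EPHA2 (0.725), FGF2 (0.875) and MYC (0.722). It was the lowest for LUM (0.767), TXNIP (0.735), PIK3IP1 (0.724), BMF (0.839) and HIST1H2BD (0.750). T348I short-title library 2 was the lowest for ANKRD1 (0.718), SPRY4 (0.714), RRS1 (0.789), RRP9 (0.758) and ASNS (0.792) and the highest for LSS (0.899). The other cases were PTPN14, lowest in T348I long-title library 1 (0.825), and DDR1, lowest in wild-type long-title library 2 (0.751). The latter library also had the highest share of unmapped reads of the wild-type libraries (8.64%, gap over range 0.711) and the lowest share of strand-assigned reads on the reverse strand (92.2%, gap over range 0.891).

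The genotype difference of 6 lists depended on the title set in camera with the preset correlation, by a test of the interaction. These were NF-kB and cytokine genes (adjusted p = 0.00147), mitochondrially encoded genes (0.0109), and ribosome biogenesis, interferon response, matrix genes and matrix proteases (0.0243 each). With an estimated correlation the smallest adjusted p over all lists was 0.820. Without wild-type long-title library 1, of these 6 lists ribosome biogenesis alone passed (adjusted p = 0.000640), and G1/S (0.00906) and cholesterol genes (0.0402) passed as well.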

How the results depend on the processing

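The unstranded counts, the fit without both wild-type libraries that stand apart, the correction for GC content and length, the summed T348I long-title libraries and the list interaction without wild-type long-title library 1 were chosen after seeing the data.

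RLE size factors, library sizes alone, DESeq2, limma-voom and a stricter filter left each count of genes within 1.5 times, and kept the calls of YES1 and of the YAP list. Without the low-count filter 661 genes changed at least 2-fold, as more low genes were tested. Without the title set term 818 genes were higher, 497 lower and 177 changed at least 2-fold, and YES1 lost its call (0.58, adjusted p = 0.126), since the spread between sets then counts as error. With fewer samples, the long-title libraries alone gave 698 higher and 499 lower genes and YES1 at 0.45, and the short-title libraries alone 935 and 599. With the T348I long-title libraries summed into 1, 899 were higher and 563 lower and YES1 lost its call (0.66, adjusted p = 0.109). Camera with an estimated correlation called 0 lists, and DESeq2 called 1 gene in the interaction, whose cause was not tested. With the preset correlation, unstranded counts and the correction for GC content and length called 11 lists each, against 12 in the main fit. Whether the replicate numbers pair the libraries stays undecided. Same-numbered libraries deviated together at correlations of -0.0253, 0.159 and 0.0745 in the long-title set and 0.217 in the short-title set. Differently numbered libraries gave -0.156 to 0.0786 in the long-title set and -0.217 in the short-title set. Deviations within so few libraries sum to 0, so the differently numbered values follow largely from the same-numbered ones. The same-numbered values were mostly above 0, but so few pairs cannot show or exclude pairing. The replicate block gave 1905 higher and 1836 lower genes and 13 lists. YES1 was at 0.61 with it (edgeR adjusted p = 0.00921).

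Leaving out each library in turn gave 1342 to 2379 higher genes, 1108 to 2297 lower genes, 276 to 446 changed at least 2-fold, YES1 between 0.42 and 0.76, a median of the YAP list between 0.31 and 0.41, 11 to 13 lists and a correlation between sets of 0.562 to 0.687. The lower genes moved most without T348I short-title library 1 (1108) and T348I long-title library 1 (1204), and the correlation without wild-type short-title library 2 (0.562). Without both wild-type libraries that stand apart the counts were 2304 and 2055 and the median of the YAP list 0.46. Uncalled members of the YAP list changed sign, and the cause was not tested. CCDC80 went to -0.10 and IGFBP3 to 0.19 in the long-title libraries alone. With each library left out IGFBP3 lay between -0.20 and 0.047, above 0 without wild-type long-title library 1 (0.047), wild-type short-title library 2 (0.018) or T348I short-title library 1 (0.038), and RBMS3 between -0.22 and 0.021, the latter without wild-type long-title library 1. Of 3524 values of named genes under the alternatives, 3072 kept direction and call, 427 lost the call, 19 gained it and 6 changed sign. Depth and the number of libraries limit small changes most.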

Other observations

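The title set contrast and the genes named for it were chosen only after the results were seen.

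With genotype in the model, 5918 genes differed between title sets, against 3709 between genotypes. The short-title libraries held less of the chemokine gene CCL20, 0.496 ± 0.240 against 43.5 ± 8.08 CPM (n = 4 and 6; log2 fold change -6.48 ± 0.24, adjusted p = 2.85e-09, edgeR). S100A9, a calcium-binding protein of inflamed tissue (-7.48 ± 0.39, adjusted p = 4.37e-08), CSF2, the gene of GM-CSF (-4.62 ± 0.61, adjusted p = 7.59e-05), and GPAM, an enzyme of glycerolipid synthesis (-6.39 ± 0.33, adjusted p = 4.63e-08), were lower too. They held more of the protease gene PRSS12, 16.8 ± 1.23 against 0.878 ± 0.658 CPM (4.23 ± 0.28, adjusted p = 2.81e-07). The glutamate receptor gene GRIN2A (3.88 ± 0.32, adjusted p = 1.70e-06) was higher as well. In all 2881 genes were higher and 3037 lower in the short-title libraries, 1141 of them at least 2-fold.

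The lists fixed for the genotype comparison also moved with the title set. Of the NF-kB and cytokine genes 0 of 21 were higher and 18 lower in the short-title libraries, with a median of -2.67 (camera adjusted p = 1.06e-11). Hypoxia and glycolysis genes (0 higher and 17 lower of 18, median -0.90, adjusted p = 3.96e-09), ER chaperones (0 and 15 of 16, -0.63, 2.03e-08), ATF4 targets (0 and 13 of 17, -0.65, 5.23e-05) and cholesterol genes (1 and 14 of 22, -0.36, 0.000634) were lower too. Mitotic genes (12 and 0 of 26, 0.22, 0.000687) and YAP targets (10 and 1 of 21, 0.27, 0.00481) were higher. In total 10 of 27 lists were called with the preset and 0 with an estimated correlation, with 0.194 as the adjusted p of the NF-kB list. The labels give no meaning to the title styles, so no biological explanation was tested. The title set term removes the mean shift between the sets from the genotype comparison, but not a genotype difference that depends on the set.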
